A study of Mus musculus with 6 samples.

How the data were processed

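RNA was extracted from mouse heart with Trizol, and libraries were made from total RNA with a NEBNext Ultra RNA kit, which does not mark the strand, and sequenced as paired reads, per the labels' protocols. The deposited table holds raw counts of reads per gene, as the authors made it, for 54532 genes in 6 libraries. FastQC 0.12.1, HISAT2 2.2.1, featureCounts 2.0.6 and the genome build mm39 are named per the submitters' processing notes, which do not give their roles or settings. The gene coordinates in the table are nevertheless those of GRCm38: of 54495 gene IDs shared with GENCODE M21, 53499 (98.17%) lay at its GRCm38 position, and coordinates are therefore printed as in the table, as GRCm38. Whether the counting used the strand, and how it treated reads that map to several places, is not given in the sources used here, so overlapping genes, antisense partners and close paralogs cannot be told apart with certainty. The table held 27 symbols turned into dates, which were restored by gene ID, and 0 rows without a gene.

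The 3 WT columns bear the titles of the 3 WT samples. The T3KO columns are numbered 1 to 3 while the titles of the T3KO samples carry an additional number, so these columns were used as replicates of the T3KO group without being tied to single samples, and "T3KO replicate 1" stands for the first numbered column. The labels list the 6 samples as separate heart samples and do not say that each came from its own animal, so p-values measure the spread between these samples. The additional number is the same in all 3 T3KO titles, and whether it marks a shared animal or line is not given in the sources used here. Total counts were 29192857 to 31218445 per library. Libraries of one group differed by more than sampling noise (chi-square per degree of freedom of 9.95 to 12.2 between pairs, over genes with at least 20 reads in the pair), so no library was a copy of another.

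Genes were filtered with filterByExpr by group, which left 15168, scaled with TMM factors, and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest with robust dispersions, R 4.3.3), T3KO against WT with 3 libraries each and no covariate, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 5% FDR. Standard errors were derived from the log2 fold change and the F statistic. CPM values are scaled by the TMM library sizes and given as mean ± SD. Folds against a group at 0 used a floor of 3 reads over the group, which, like other counting limits, covers counting error only. Of the 39 gene lists fixed beforehand, the 38 with at least 3 tested members were tested with limma 3.58.1 (camera on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists). Older symbols in the table (Ctgf, Cyr61, Wisp2) were matched to listed newer ones. A list's score in a library is the mean over its tested members of log2 CPM minus the WT mean. The mean, median and camera direction of a list differed in sign for 10 lists, none of them called: fatty acid oxidation; T and NK cells; unfolded protein and integrated stress response; fetal gene programme and hypertrophy markers; erythroid cells; BMP, GDF and activin pathway; renin-angiotensin, endothelin and natriuretic signalling; antigen presentation; apoptosis, necroptosis and pyroptosis; and oxidative stress response.

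The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names the 3 TGF-beta ligand genes; the 12 genes that rose and the 12 that fell with the smallest p among called genes with non-overlapping groups, a mean of at least 1 CPM in one group and an official symbol that is not a predicted model or pseudogene; up to 4 called members of each list, or up to 2 with the smallest p, as values, where none was called; and sex-linked and transgene readout genes. The alternatives were RLE or upper-quartile factors, libraries without mitochondrially encoded and globin genes, no low-count filter, a filter of 1 CPM in 3 libraries, each library left out in turn, DESeq2 1.42.0, limma-voom, fits without robust dispersions, protein-coding genes alone, and for the lists an estimated correlation, ranks, and fry. A correction for gene length and GC content, fitted per library as a smooth curve with 4 degrees of freedom each, was added after the data were seen.

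The steps were tested on simulated data. In 5 simulated sets of counts with the means and library sizes of these samples and known changes, the edgeR test of T3KO against WT, run on 14906 to 14928 genes, recovered 15.6% of genes changed 1.25-fold, 51% of those changed 1.5-fold, 74.5% at 2-fold and 93.4% at 4-fold, and 77 of its 650 calls (11.8%) were genes that had not been changed, more than the nominal 5%. The camera test called 5 of 5 shifted lists and 0 of 33 unshifted ones, on 14917 genes drawn without correlation between them. At this depth and number of libraries, changes under 1.5-fold are thus often missed.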

Results

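RNA from heart tissue was sequenced in 6 mouse libraries, 3 from wild-type (WT) hearts and 3 from hearts labelled T3KO, in which Tgfb3, the gene of the secreted cytokine transforming growth factor beta 3, was deleted conditionally in cardiomyocytes. The series design speaks of an operation abbreviated TAC, in heart research the usual short form of transverse aortic constriction, which narrows the aorta and raises the load on the left ventricle. The sample labels give genotype alone, so whether the WT hearts were operated on is not given in the sources used here. The one comparison this design implies asks how gene expression in the heart differed between the genotypes. The libraries held between 29192857 and 31218445 counted reads and between 20802 and 21362 genes with at least 1 read. Mitochondrially encoded genes took 24.2% to 25.9% of the reads. Pearson's r of log2 CPM (read counts scaled to library size) across genes was 0.9837 to 0.9858 between libraries of one genotype and 0.9803 to 0.9842 between genotypes. The Y-linked gene Ddx3y was at 63.8 to 82.9 CPM in all 6 libraries, Eif2s3y at 34.1 to 55 CPM, Kdm5d at 12 to 15.8 CPM and Uty at 16.1 to 20.7 CPM. Xist, the RNA that silences an X chromosome in female cells, reached at most 8 reads in a library.

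The targeted gene fell in the T3KO hearts. Tgfb3 (ENSMUSG00000021253, chromosome 12, 86056745 to 86079041, GRCm38) was at 19.6 ± 1.195 CPM in WT (SD, n = 3) and at 14.7 ± 0.80 CPM in T3KO (SD, n = 3). Its log2 fold change was -0.41 ± 0.10 (SE), with an adjusted p of 0.0408 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its counts were 630, 593 and 602 in the WT libraries and 419, 407 and 482 in the T3KO libraries, so 3 of 3 T3KO libraries lay below every WT library. Such a separation of the groups held for 19.5% of all genes tested. The counts cover the whole gene and all cells of the sampled tissue, so reads from other cells and from exons that were not deleted remain in them. The fall thus does not by itself show the deletion in cardiomyocytes. The paralog Tgfb1 did not pass, at 31.8 ± 1.21 CPM in WT and 27.9 ± 0.89 CPM in T3KO (log2 fold change -0.19, adjusted p = 0.272), nor did Tgfb2, at 19.1 ± 1.07 CPM and 16.2 ± 3.70 CPM (-0.24, adjusted p = 0.459). For Tgfb1, too, 3 of 3 T3KO libraries lay below every WT library. For Tgfb2 the log2 fold change was -0.45 without T3KO replicate 3 (adjusted p = 0.0862) and -0.13 without T3KO replicate 2 (adjusted p = 0.731). The Tgfb3 call ended when WT replicate 1, WT replicate 3 or any 1 T3KO library was left out (log2 fold change -0.46 to -0.37, adjusted p = 0.069 to 0.175), in limma-voom (adjusted p = 0.0641) and without robust dispersions (adjusted p = 0.066).

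Esr1, the estrogen receptor gene whose ligand-binding domain is part of the tamoxifen-inducible recombinase MerCreMer, was read as a transgene readout. Esr1 (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614) held 30, 95 and 20 reads in the WT libraries and 83598, 80077 and 86635 reads in the T3KO libraries, or 1.53 ± 1.24 CPM against 2825 ± 39.7 CPM (SD, n = 3 each; log2 fold change 10.83, adjusted p = 0.00295). The mouse growth hormone gene, Gh, was read because some Cre cassettes hold a growth hormone polyadenylation signal. It had 0 reads in all 6 libraries, below the floor of 3 reads over a group. A signal taken from another species might not be counted at the mouse gene, so this decides nothing about a cassette. Esr1 reads were thus high in T3KO alone, so the WT libraries offer no control for a transgene that carries Esr1 sequence. Its effects and those of the deletion cannot be told apart for any gene called. Whether the WT animals carried another Cre transgene or were given tamoxifen is not given in the sources used here. On chromosome 19 (GRCm38), A1cf, the gene of an RNA-editing cofactor (31868764 to 31948573), had 0 reads in the 3 WT libraries and 53, 76 and 86 in the T3KO libraries, at least 75.5-fold higher against a floor of 3 reads over the WT group. The predicted gene Gm19241 lies within A1cf. Lipo4, a lipase-family gene (33498037 to 33517780), had 0 reads in WT and 57, 46 and 60 in T3KO, at least 57.2-fold higher, and Lipo2 (33719670 to 33769142) rose from 0.246 ± 0.129 to 6.41 ± 0.964 CPM. Lipo3 lay lower in 3 of 3 T3KO libraries, at 9.66 ± 0.301 CPM in WT and 5.22 ± 2.09 CPM in T3KO, but did not pass (adjusted p = 0.0939). Lipo2 overlaps Lipo3 and belongs to a multigene family, so its reads and those of Lipo4 are uncertain in origin.

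**Figure D1:**
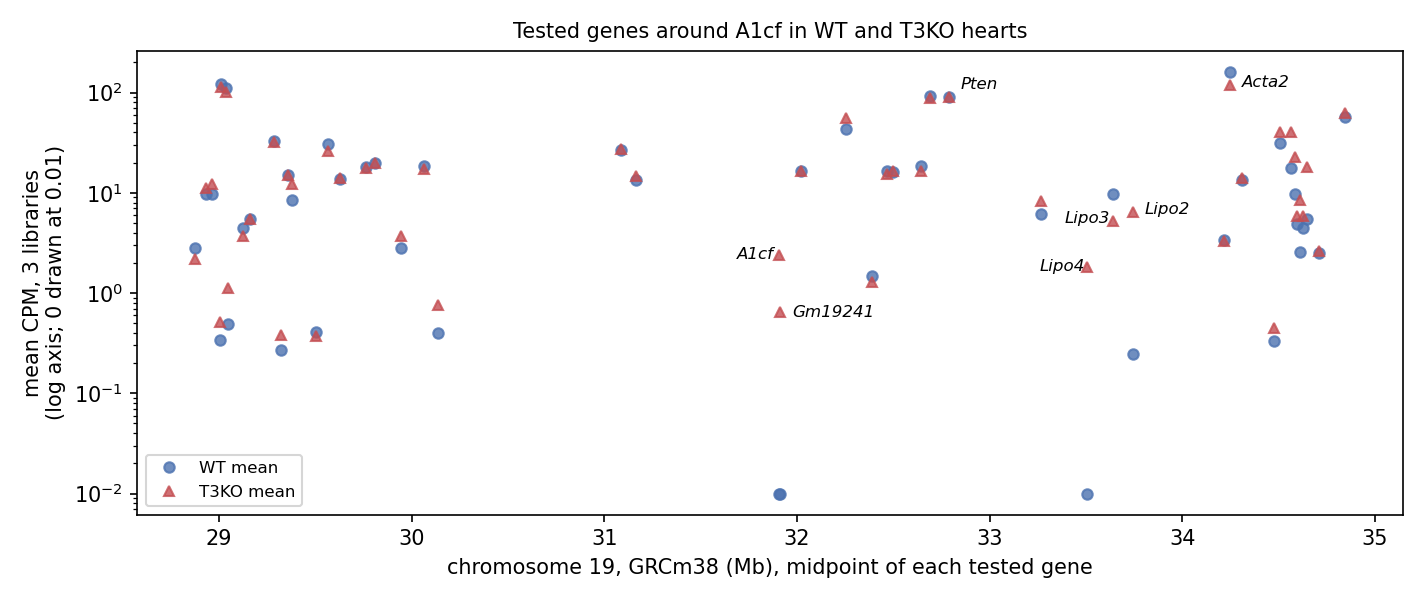
Tested genes on chromosome 19 (GRCm38) around A1cf, with the position in Mb on the horizontal axis and the mean CPM of 3 libraries on a logarithmic vertical axis, WT as circles and T3KO as triangles, with a mean of 0 drawn at 0.01. A1cf, Gm19241 and Lipo4 had no WT reads, and Lipo2 was at 0.246 CPM in WT and 6.41 CPM in T3KO.

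Of 15168 genes tested, 285 passed 5% FDR, of which 131 rose and 154 fell in T3KO. The changes were mostly small. The median absolute log2 fold change of the called genes was 0.42, and 26 of them changed at least 2-fold, 18 upward and 8 downward. All 285 had WT and T3KO libraries that did not overlap, as did 2954 of the tested genes (19.5%, where chance gives 10%). The genes that rose with the smallest p were led by Ctgf, the gene of the matricellular protein connective tissue growth factor (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683), which went from 82.8 ± 6.01 to 225.7 ± 12.7 CPM (log2 fold change 1.45 ± 0.06, adjusted p = 2.13e-10). Next came the immediate early response gene Ier5 (1.47 ± 0.07, adjusted p = 5.86e-10) and the deubiquitinase gene Otud1 (1.75 ± 0.09, adjusted p = 5.53e-09). Lipo2, A1cf and Lipo4, described above, belong to the same 12. The insulin receptor substrate gene Irs2 rose by 1.52 ± 0.13 on the log2 scale, and the Krüppel-like transcription factor genes Klf2 by 0.96 ± 0.09 and Klf6 by 0.64 ± 0.07. Rhobtb1, an atypical Rho GTPase gene, rose by 0.70 ± 0.07, the FERM domain gene Frmd5 by 0.54 ± 0.05, and Lmod2, whose product lengthens the thin filaments of heart muscle, from 679.8 ± 28.3 to 977.8 ± 24.0 CPM.

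The 12 genes that fell with the smallest p were led by Eln, the gene of elastin (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323), which went from 66.6 ± 6.09 to 37.7 ± 1.84 CPM (log2 fold change -0.82 ± 0.08, adjusted p = 8.05e-06). Cldn5, which encodes an endothelial tight junction protein (ENSMUSG00000041378, chromosome 16, 18776847 to 18778262), went from 39.7 ± 2.94 to 20.95 ± 1.505 CPM (-0.92 ± 0.09, adjusted p = 8.05e-06). Fbn1, the gene of the microfibril protein fibrillin, fell by 0.65 on the log2 scale and Col15a1, a collagen of the basement membrane zone, fell by 0.74. The transcription factor gene Klf10, which TGF-beta is known to induce, fell by 0.99, the gene of the YAP partner Tead1 fell by 0.49, and the cell cycle inhibitor gene Cdkn1a fell by 0.54. Xirp2, an actin-binding protein gene of the intercalated disc, went from 1544 ± 103 to 1038 ± 83.9 CPM, and Fstl1, the gene of a secreted glycoprotein, from 143 ± 8.64 to 101.5 ± 5.67 CPM. Tuba8 (log2 fold change -0.44), Rflnb (-0.77) and Afdn (-0.42) complete this set. Each of these 12 genes and of the 12 that rose passed 5% FDR in each alternative that gave it a value. The number of calls was 122 without T3KO replicate 3, 138 without WT replicate 1 and 187 without T3KO replicate 1. It was 453 with DESeq2 and 651 without a low-count filter.

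**Figure D2:**
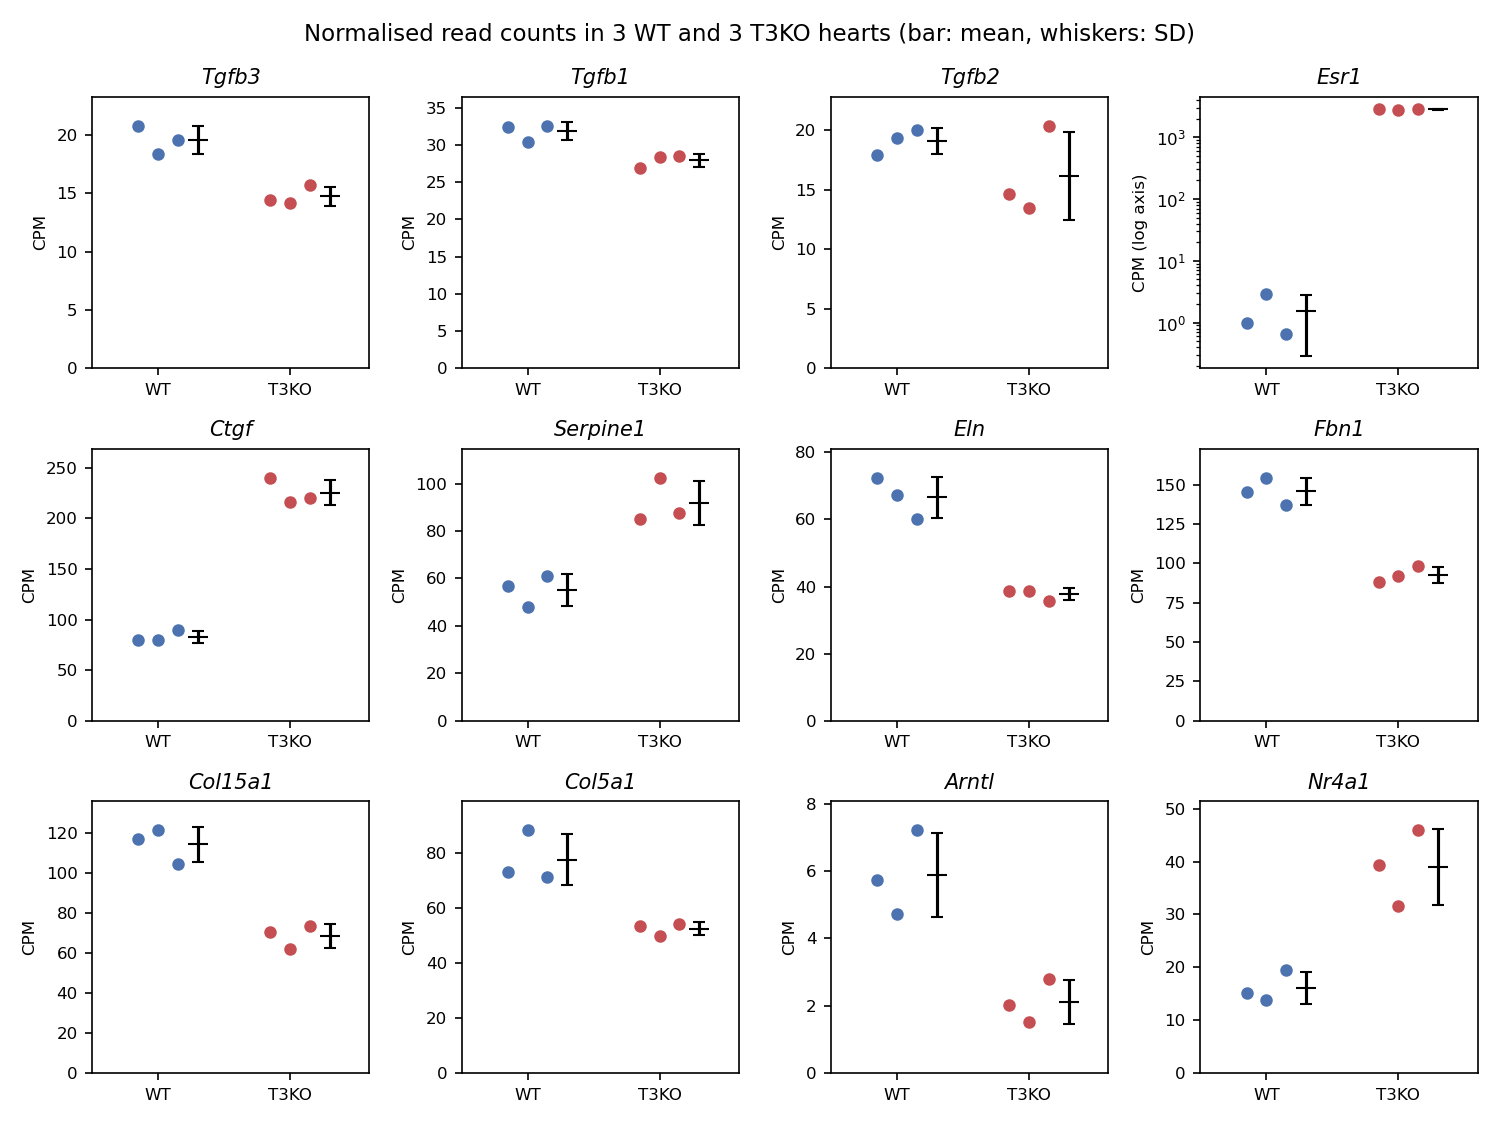
Normalised read counts (CPM, vertical axis, linear from 0 except for Esr1, whose axis is logarithmic) of 12 genes in 3 WT and 3 T3KO heart samples (horizontal axis), one point per library, with the mean as a bar and the SD as whiskers. Ctgf lay at a mean of 82.8 CPM in WT and 225.7 CPM in T3KO, and Tgfb3 at 19.6 and 14.7 CPM.

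Collagen genes were lower in T3KO hearts. Of 18 collagen genes tested, 0 rose and 11 fell over all genes tested, and 14 fell when adjusted over the list alone. All 18 had negative log2 fold changes under each scaling tried, with a mean of -0.43. Col15a1 went from 114.1 ± 8.63 to 68.4 ± 6.01 CPM, Col5a1 from 77.6 ± 9.34 to 52.5 ± 2.39 CPM. The basement membrane collagens moved too, Col4a1 from 836 ± 55.0 to 644 ± 18.05 CPM and Col4a2 from 692 ± 28.7 to 537 ± 14.25 CPM (SD, n = 3 each). The collagen list was lower than other genes in limma's camera test at a preset correlation (adjusted p = 6.63e-12), but not with an estimated correlation (adjusted p = 0.815). Lists of vessel cells had negative means too, pericytes and smooth muscle -0.13 and endothelial cells -0.15, as given below. Of 24 matricellular and other matrix proteins, 0 rose and 3 fell, namely Eln, Fbn1 and the proteoglycan gene Vcan (log2 fold change -0.54). Adjusted over the list alone, 2 rose and 7 fell (camera adjusted p = 0.192). Of 21 matrix crosslinking and remodelling enzymes, the protease gene Adamts1 rose (from 41.9 ± 5.38 to 80.7 ± 8.55 CPM) and the lysyl oxidase family gene Loxl1 fell (from 64.0 ± 1.42 to 45.5 ± 6.68 CPM). In that list 1 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.213). Of 11 myofibroblast markers, the transcription factor gene Meox1 fell (-0.73), and 2 fell when adjusted over the list alone (camera adjusted p = 0.476). None of 12 resident fibroblast markers passed by edgeR over all genes and 1 fell when adjusted over the list alone (camera adjusted p = 0.575). Ddr2 was at 27.2 ± 0.66 and 22.3 ± 1.36 CPM and Gpx3 at 166 ± 21.9 and 242.5 ± 38.2 CPM in WT and T3KO. Vcan did not pass without WT replicate 3 or T3KO replicate 2 (adjusted p = 0.0566 to 0.0732), nor Meox1 without WT replicate 1 or any 1 T3KO library, in limma-voom or without robust dispersions (adjusted p = 0.0619 to 0.141). Camera called the matrix protein list lower without WT replicate 3 (adjusted p = 0.0117) or T3KO replicate 3 (adjusted p = 0.034), and the enzyme list lower without T3KO replicate 3 (adjusted p = 0.034).

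Genes of the TGF-beta pathway moved in both directions. Of 15 target genes of the pathway tested, 2 rose and 2 fell over all genes tested, and 4 rose and 3 fell when adjusted over the list alone. Ctgf and Serpine1, the gene of plasminogen activator inhibitor, rose, the latter from 55.3 ± 6.77 to 91.7 ± 9.35 CPM, while Klf10 and the transcription factor gene Bhlhe40 (61.9 ± 5.27 to 47.0 ± 4.88 CPM) fell. Tgfb3 itself was the 1 gene to fall among 14 ligands, receptors and SMADs, over all genes and when adjusted over the list alone, and 0 rose. Fstl1 was the 1 gene to fall among 17 genes of the BMP, GDF and activin pathway, of which 1 rose and 1 fell when adjusted over the list alone. Camera called none of the lists (adjusted p = 0.326 for the targets, 0.57 for the ligands, receptors and SMADs, 0.84 for BMP, GDF and activin). Bhlhe40 did not pass without WT replicate 1 or 3 or T3KO replicate 1 or 2, nor in limma-voom (adjusted p = 0.0509 to 0.0884).

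Genes of the cardiomyocyte changed in both directions. Of 14 fetal and hypertrophy markers, 0 rose and 2 fell, Xirp2 and the calcineurin regulator gene Rcan1 (112.8 ± 13.5 to 79.7 ± 2.68 CPM), and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.794). Of 19 adult sarcomere genes, Tcap, the gene of the Z-disc protein telethonin, rose from 1817 ± 106 to 2204 ± 110.1 CPM, alone also when adjusted over the list alone (camera adjusted p = 0.27). Of 25 calcium handling and ion channel genes, Kcnip2, whose product modulates the transient outward potassium current, rose from 131.3 ± 7.33 to 177.6 ± 18.9 CPM and the inward rectifier gene Kcnj2 fell from 53.4 ± 6.28 to 34.8 ± 4.52 CPM. Adjusted over the list alone, 3 rose and 1 fell (camera adjusted p = 0.355). Of 15 genes of renin-angiotensin, endothelin and natriuretic signalling, the beta-adrenergic receptor gene Adrb1 fell from 23.7 ± 3.045 to 15.8 ± 1.51 CPM, 1 also when adjusted over the list alone (camera adjusted p = 0.84). Of 4 atrial markers 0 passed by either adjustment (camera adjusted p = 0.575), with Myl4 at 2.44 ± 0.59 and 1.76 ± 0.59 CPM and Nppa at 114.6 ± 23.8 and 127.1 ± 14.6 CPM in WT and T3KO. Tcap did not pass without WT replicate 3, T3KO replicate 1 or T3KO replicate 3 (adjusted p = 0.0675 to 0.0962), nor Adrb1 without WT replicate 1 (adjusted p = 0.0507).

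Among genes of energy metabolism and of the ribosome, 1 passed 5% FDR over all genes tested. Of 35 nuclear oxidative phosphorylation subunits, 0 passed over all genes or when adjusted over the list alone, while 30 had positive log2 fold changes with a mean of 0.05. Atp5b was at 4743 ± 110.5 CPM in WT and 5244 ± 142.5 CPM in T3KO, and Ndufv1 at 677.5 ± 15.4 and 752.5 ± 27.6 CPM. Camera called this list higher at the preset correlation (adjusted p = 0.0332) but not with an estimated correlation (adjusted p = 0.817). Of 44 cytosolic ribosomal proteins, 39 had positive log2 fold changes, with a mean of 0.06, and the 1 that passed, over all genes and when adjusted over the list alone, was Rpl30, which fell (-0.34 ± 0.08). Camera called the list higher (adjusted p = 0.00306), but not with an estimated correlation (adjusted p = 0.817), and reads of ribosomal protein genes can be shared with processed pseudogenes. By either adjustment 0 genes passed among 24 of fatty acid oxidation (camera adjusted p = 0.284), 19 of glycolysis (0.213) and 13 mitochondrially encoded mRNAs (0.396). Cpt1b was at 2.24 ± 0.42 and 3.68 ± 0.52 CPM and Acadm at 1047 ± 20.2 and 1139 ± 21.4 CPM in WT and T3KO. Pfkl was at 133.5 ± 9.59 and 149.4 ± 3.94 CPM and Slc2a4 at 409 ± 25.8 and 449.8 ± 10.5 CPM, mt-Nd6 at 5788 ± 521 and 6475 ± 198 CPM and mt-Atp8, which overlaps mt-Atp6, at 1.90 ± 0.34 and 3.02 ± 0.30 CPM in WT and T3KO. The oxidative phosphorylation call ended without any 1 WT library or T3KO replicate 1, with upper-quartile factors and without a low-count filter (adjusted p = 0.0536 to 0.217), and the ribosomal call without WT replicate 1 (adjusted p = 0.0705). Rpl30 did not pass without WT replicate 1 or 2, T3KO replicate 1 or 2 or robust dispersions, nor in limma-voom (adjusted p = 0.0864 to 0.173). After a length and GC correction its log2 fold change was -0.31, against -0.34 before, and it did not pass (adjusted p = 0.106). The same correction, added after the data were seen, brought the mean log2 fold change of the oxidative phosphorylation list to 0.02 (adjusted p = 0.495) and that of the ribosomal list to 0.03 (adjusted p = 0.149).

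Of 16 immediate early and dissection stress genes tested, 4 rose and 0 fell over all genes tested, 6 rose and 0 fell when adjusted over the list alone, and 15 had positive log2 fold changes with a mean of 0.70. Atf3, a stress-induced transcription factor gene, went from 2.94 ± 1.39 to 11.3 ± 2.07 CPM, the nuclear receptor gene Nr4a1 from 16.13 ± 3.003 to 39.0 ± 7.23 CPM. Zfp36, whose product destabilises mRNAs, went from 26.2 ± 5.97 to 54.6 ± 4.37 CPM, and Ier3 from 23.4 ± 3.08 to 39.3 ± 4.68 CPM. Camera called the list (adjusted p = 5.14e-07), but not with an estimated correlation (adjusted p = 0.815). The list holds genes that rise within minutes of dissection, and its mean score per library, in log2 units above the WT mean, spread from -0.42 to 0.51 in WT and from 0.68 to 0.88 in T3KO. Nr4a1 did not pass without WT replicate 1 (adjusted p = 0.146), Atf3 without WT replicate 1 or T3KO replicate 2 (adjusted p = 0.0526 to 0.0615), or Zfp36 without WT replicate 2, T3KO replicate 2 or T3KO replicate 3 (adjusted p = 0.0765 to 0.14).

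Clock genes changed in opposite directions. Of 14 tested, 2 rose and 2 fell over all genes, and 8 rose and 4 fell when adjusted over the list alone. Arntl, the gene of the clock's activator BMAL, fell from 5.89 ± 1.254 to 2.11 ± 0.65 CPM and its partner Clock from 43.2 ± 3.57 to 28.9 ± 3.91 CPM. The output regulators Tef (161.7 ± 20.2 to 231.1 ± 9.96 CPM) and Dbp (78.2 ± 10.03 to 101.7 ± 2.70 CPM) rose. Of 16 angiogenesis and hypoxia genes, 3 fell and 0 rose, the oxygen sensor gene Egln3 (log2 fold change -0.48), the peptide ligand gene Apln (-0.80) and the angiopoietin gene Angpt1 (-0.42). In this list 5 fell when adjusted over the list alone. Of 17 unfolded protein and integrated stress response genes, the transcription factor gene Atf4 rose (0.39) and the chaperone gene Hspa5 fell (-0.24), and 1 rose and 2 fell when adjusted over the list alone. Of 18 cell death genes, Cdkn1a fell by either adjustment and no other passed. By either adjustment 0 of 20 cell cycle genes passed by edgeR and 0 of 15 oxidative stress genes. Mki67 was at 5.24 ± 1.98 and 3.28 ± 0.46 CPM and Top2a at 3.46 ± 1.77 and 1.855 ± 0.61 CPM, Srxn1 at 21.6 ± 0.50 and 18.5 ± 2.15 CPM and Sod1 at 179.7 ± 6.36 and 194.0 ± 12.98 CPM in WT and T3KO. Camera called none of these lists (adjusted p = 0.0971 for the clock, 0.0962 for angiogenesis and hypoxia, 0.794 for the stress responses, 0.846 for cell death, 0.192 for the cell cycle and 0.947 for oxidative stress). It called the clock list higher without WT replicate 2 (adjusted p = 0.0286) and the cell cycle list lower without WT replicate 3 (adjusted p = 0.0117) or T3KO replicate 1 (adjusted p = 0.0208). Dbp did not pass without WT replicate 1 or 3 or any 1 T3KO library (adjusted p = 0.059 to 0.116), nor Egln3 without T3KO replicate 3 (0.0563), Apln without T3KO replicate 2 or 3 (0.0517 to 0.0725). Angpt1 did not pass without WT replicate 2 or 3, T3KO replicate 1 or 3 or robust dispersions, nor in limma-voom (adjusted p = 0.0766 to 0.17). After the length and GC correction its log2 fold change was -0.37, against -0.42 before, and it did not pass (adjusted p = 0.0596). Hspa5 did not pass without WT replicate 1 or 3, T3KO replicate 2 or 3 or robust dispersions (adjusted p = 0.0538 to 0.107).

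Among markers of vessel and epicardial cells, 1 passed 5% FDR over all genes tested. Of 13 endothelial markers, Cldn5 fell, and 2 fell when adjusted over the list alone (camera adjusted p = 0.0634, and 0.0117 without WT replicate 3). Of 10 pericyte and smooth muscle markers, 0 passed by either adjustment and 1 had a positive log2 fold change, with a mean of -0.13. Rgs5 was at 627 ± 31.6 and 555.7 ± 52.6 CPM and Pdgfrb at 96.7 ± 13.5 and 81.2 ± 5.33 CPM in WT and T3KO. Camera called the pericyte list lower (adjusted p = 0.0427), but not with an estimated correlation (adjusted p = 0.817). Of 9 epicardial and mesothelial markers, 0 passed by either adjustment and all 9 had positive log2 fold changes, with a mean of 0.56. Camera called the list higher (adjusted p = 0.0259), but not with an estimated correlation (adjusted p = 0.817). Msln was at 2.94 ± 0.90 and 4.71 ± 0.49 CPM and Krt19 at 0.63 ± 0.19 and 1.18 ± 0.13 CPM in WT and T3KO. The mean score of the list was -0.50 in WT replicate 1, 0.32 and 0.18 in the other WT libraries and 0.33 to 0.65 in T3KO. The pericyte call ended without WT replicate 2 or 3 or T3KO replicate 1, with upper-quartile factors and without a low-count filter (adjusted p = 0.0536 to 0.224, with a mean of -0.09 without T3KO replicate 1), and the epicardial call without WT replicate 1 (mean 0.34, adjusted p = 0.236) or T3KO replicate 2 (mean 0.38, adjusted p = 0.0724).

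Among immune lists, Cxcl12 fell (162.3 ± 10.6 to 133.9 ± 4.29 CPM) as the 1 called gene of 15 cytokines and chemokines, over all genes and when adjusted over the list alone (camera adjusted p = 0.213 for the list). It did not pass without WT replicate 1 or 3 or T3KO replicate 1 or 3 (adjusted p = 0.0738 to 0.097). Of 11 antigen presentation genes 0 passed over all genes and 1 fell when adjusted over the list alone (camera adjusted p = 0.844). H2-Ab1 was at 29 ± 2.44 and 23.6 ± 0.59 CPM and H2-Eb1 at 34.4 ± 7.53 and 26.4 ± 1.59 CPM. By either adjustment 0 genes passed by edgeR among 20 macrophage and monocyte markers (camera adjusted p = 0.993), 8 of T and NK cells (0.575), 10 of B and plasma cells (0.904), 3 of neutrophils (0.575), 6 of erythroid cells (0.84), 5 of Schwann cells and neurons (0.84) and 4 of skeletal muscle (0.57). The macrophage and monocyte genes with the smallest p were Cx3cr1, at 5.07 ± 1.49 and 2.51 ± 1.16 CPM, and Ccr2, at 4.08 ± 0.84 and 2.73 ± 0.64 CPM in WT and T3KO. For T and NK cells Il2rb was at 1.155 ± 0.178 and 0.649 ± 0.226 CPM and Lck at 0.621 ± 0.232 and 0.371 ± 0.173 CPM. For B cells Cd19 was at 1.579 ± 0.704 and 1.104 ± 0.544 CPM and Ms4a1 at 0.669 ± 0.496 and 0.998 ± 0.729 CPM. For neutrophils Csf3r was at 2.17 ± 0.934 and 1.457 ± 0.341 CPM and S100a9 at 1.121 ± 0.859 and 0.718 ± 0.279 CPM. For erythroid cells Slc4a1 was at 1.091 ± 0.412 and 1.454 ± 0.523 CPM and Hbb-bs at 579.7 ± 68.4 and 514.7 ± 85.9 CPM. For Schwann cells and neurons Sox10 was at 1.521 ± 0.421 and 1.042 ± 0.495 CPM and Mbp at 2.34 ± 0.720 and 3.11 ± 1.165 CPM. For skeletal muscle Mylpf was at 0.7955 ± 0.143 and 0.5796 ± 0.234 CPM and Atp2a1 at 0.525 ± 0.0614 and 0.666 ± 0.0267 CPM. None of the 8 adipocyte markers had enough reads to be tested. Of 15 interferon-stimulated genes 0 passed by either adjustment (camera adjusted p = 0.157). Ifit2 was at 17.58 ± 1.202 and 40.4 ± 34.95 CPM and Usp18 at 3.32 ± 0.95 and 9.21 ± 9.71 CPM. One library stood apart in this list, T3KO replicate 1, whose mean score was 2.33 log2 units above the WT mean against -0.46 to 0.10 in the other 5 libraries. Without T3KO replicate 1 the interferon list turned, with a mean log2 fold change of -0.33 (camera adjusted p = 0.0208). It was called higher without T3KO replicate 2 (1.55, adjusted p = 0.0133) or T3KO replicate 3 (1.56, adjusted p = 0.00346). None of the 6 camera calls held with an estimated correlation, and fry, which asks without regard to other genes whether a list shifted in one direction, called 0 of 38 lists (7 at an unadjusted p under 0.05). Its test for changes in either direction called 22.

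**Figure D3:**
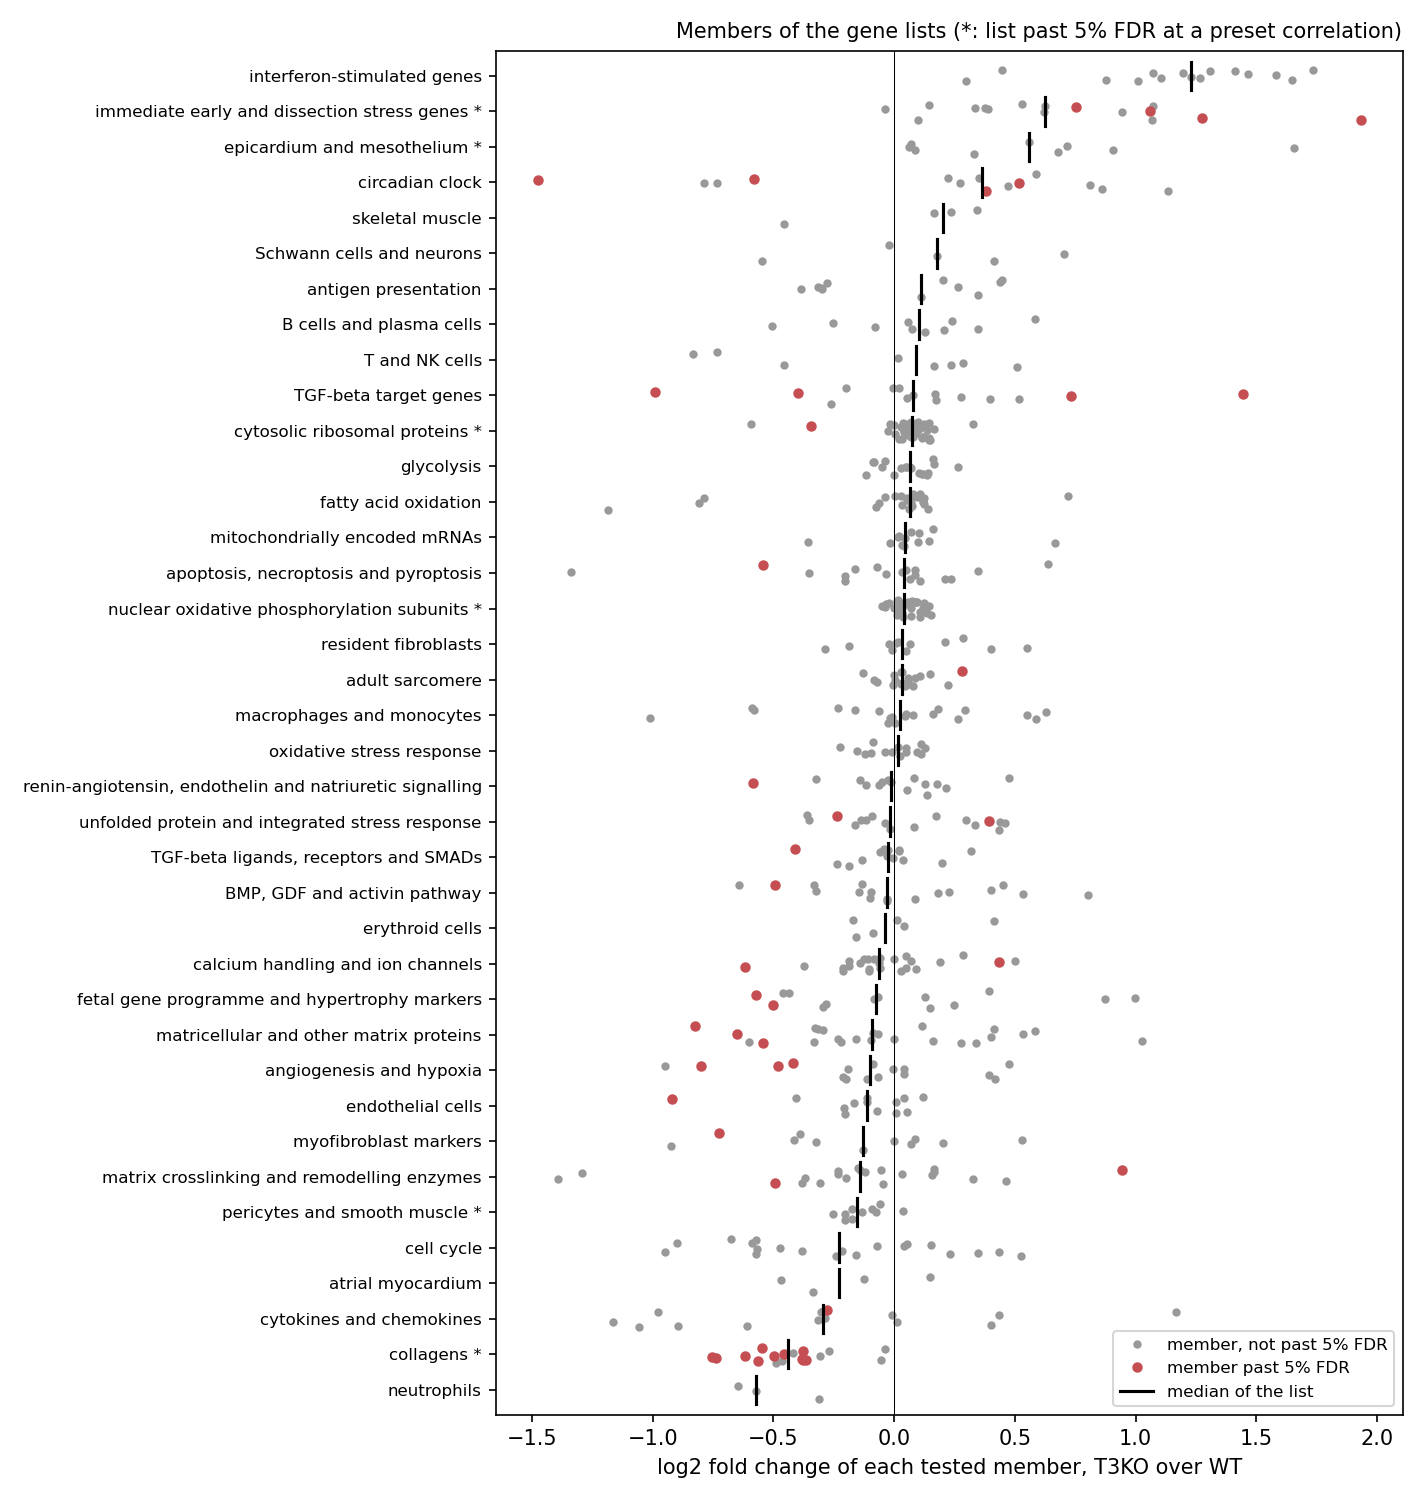
Log2 fold change, T3KO over WT, of each tested member (horizontal axis) of the 38 gene lists (vertical axis), with members past 5% FDR in red, others in grey and the median of each list as a black bar. All 18 collagens lie below 0, and the clock and TGF-beta target lists hold called genes on both sides of it.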

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

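The length and GC correction was chosen after the data were seen. No paired analysis was possible because the numbers of the T3KO columns do not name single samples, so the planned fit with a replicate block was not run. The number of genes past 5% FDR stayed within 1.5 times of 285 with RLE or upper-quartile factors, without mitochondrial and globin genes, with the stricter filter, with protein-coding genes alone, without robust dispersions, in limma-voom and after the length and GC correction. It was 651 (292 rose, 359 fell) without a low-count filter and 453 (217 rose, 236 fell) with DESeq2, which kept 265 of the 285 genes. Without robust dispersions 105 rose and 95 fell, and in limma-voom 111 rose and 92 fell, against 131 and 154. More genes thus rose than fell in these settings, the reverse of the main fit. The cause was not tested in these cases. With 1 library left out, the calls ranged from 122 to 387 (56 to 193 rose, 66 to 194 fell), lowest without T3KO replicate 3, where 117 of the 285 genes were kept. The log2 fold change of Tgfb3 stayed negative throughout. It was -0.41 in limma-voom and without robust dispersions, where it did not pass (adjusted p = 0.0641 and 0.066), and -0.46 to -0.37 with 1 library left out, passing then only without WT replicate 2 (adjusted p = 0.0378). Its adjusted p spanned 0.0112 to 0.175 over the alternatives, and the cause was not tested beyond the loss of a library. The 6 gene lists past 5% FDR became 0 with an estimated correlation (0 lists at an unadjusted p under 0.05) and 0 by fry's test of a shift in one direction (7 lists at an unadjusted p under 0.05, while 22 passed its test for either direction), and 3 to 9 with 1 library left out, fewest without WT replicate 1. The estimate put the correlation between members at 0.43 for collagens against the preset 0.01, and the cause was not tested further. A tally over 55 named genes covers Tgfb1, Tgfb2 and the called ones that the rule named by smallest p or from a list. It leaves out Tgfb3, whose losses are given above, and the called genes Esr1, Gm19241, Klf15, Lipa and Papln. Of 546 values of the 55 under the other alternatives, 536 kept their direction and side of the threshold and 10 no longer passed. Of 330 values with 1 library left out, 286 did so and 44 no longer passed. For the 6 called lists these numbers were 36 of 54 and 26 of 36, and none of these 55 genes and 6 lists reversed. Named genes of lists without a call were not followed over the alternatives. DESeq2 gave no adjusted p for Lipo2, A1cf, Lipo4 and Arntl. With 3 libraries against 3 there are 10 splits, too few for a share under 5%: the real split gave 285 genes, as many as 1 of the 10 splits including itself, and the highest other gave 1. For the lists 4 of the 10 splits, the real one included, gave at least 6, and the highest other gave 8.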

Other observations

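The genes in the next paragraph were chosen after their values were seen, as were the tests of the insertion site, of a strain segment, of both clock explanations, of fewer fibroblasts or vessel cells and of a Cre transgene as a source of the lower collagens.

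Of 13 Krüppel-like transcription factor genes tested, 3 rose (Klf2, Klf6 and Klf15), 1 fell (Klf10) and 9 did not pass by edgeR. Klf15, a regulator of metabolism in heart muscle, rose from 47.1 ± 4.52 to 71.97 ± 7.84 CPM (SD, n = 3 each; adjusted p = 0.00141). Klf9 was at 103.1 ± 6.79 and 101.6 ± 9.62 CPM, and Klf4 at 43.9 ± 7.62 and 63.6 ± 6.39 CPM (adjusted p = 0.0811). Of the markers of a loaded heart, Myh7, the gene of the slow myosin heavy chain, was at 331.8 ± 59.5 CPM in WT and 661.1 ± 131.5 CPM in T3KO, higher in 3 of 3 T3KO libraries but not past the threshold (adjusted p = 0.179). Nppb, the gene of the brain natriuretic peptide, was at 191.5 ± 61.0 and 350.3 ± 37.2 CPM (adjusted p = 0.32). Nppa was at 114.6 ± 23.8 and 127.1 ± 14.6 CPM (adjusted p = 0.808). These genes belong to the 14 fetal and hypertrophy markers, of which 0 rose and 2 fell, with a median log2 fold change of -0.075. Groups did not overlap for 19.5% of all tested genes. The interferon-stimulated gene Ifit1 was at 47.3, 4.15 and 3.12 CPM in T3KO replicates 1, 2 and 3 and at 5.25, 6.24 and 4.91 CPM in the WT libraries.

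Of the 5 genes called at a fold of at least 4, 4 lay within one window of 3 Mb on chromosome 19, namely A1cf, Gm19241, Lipo4 and Lipo2, and the other was Esr1. The lowest Esr1 value in T3KO was 947 times the highest in WT, as a transgene carrying Esr1 sequence, such as MerCreMer, would give. The gathering in one window had a permutation p of 0.0001, the smallest that 10000 permutations can give, but it restates what was seen and counts Gm19241 apart from A1cf, within which it lies, and permutations reached 3, so it supports no explanation. As background, the MerCreMer transgene of a widely used line is registered as an allele of A1cf, while the line used here is not given in the sources used here. An insertion site near A1cf and a segment of another strain around it cannot be told apart without genotypes: of 45 other tested genes within 3 Mb, 1 passed 5% FDR (Lipa, log2 fold change 0.36, adjusted p = 0.0363). Around Tgfb3, 1 of 65 other tested genes within 3 Mb passed by edgeR (Papln, log2 fold change -0.72, adjusted p = 0.00203). A strain segment around Tgfb3 was not excluded either.

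The clock genes parted in 2 arms. The mean log2 fold change was -0.61 over Arntl, Clock, Npas2 and Cry1 and 0.45 over 10 genes of the opposite arm, a difference of 1.06 with an exact permutation p of 0.014 over 1001 arrangements of the genes, which are not independent replicates. The arms were set after the values of these genes were seen, so this supports no explanation, and Cry1 (0.35) and Nr1d1 (-0.79) went against their arms. Hearts taken at different clock phases and an effect of the genotype on the clock cannot be told apart without collection times: the contrast of the arms was 3.29 to 3.69 in T3KO libraries and 2.08 to 2.84 in WT, with 0 WT libraries within the T3KO range.

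For the lower collagens, the tables argue against a gene length or GC bias as the whole cause. After each library's trend was removed, the mean log2 fold change of the list was -0.42, against -0.43 before (camera adjusted p = 1.03e-11, in a range of 6.85e-13 to 0.815 over the alternatives). The lists of resident fibroblasts, pericytes and smooth muscle cells, and endothelial cells fell less than the collagens or not at all. The rule for this comparison was set after the values were seen, so it decides nothing about a loss of these cells. The medians of their lists were 0.032, -0.153 and -0.111, against -0.44 for the collagens, with SDs of 0.24, 0.086 and 0.271 between members. These SDs describe the spread of marker genes and are no error of a cell fraction. The myofibroblast list, with a median of -0.131 and an SD of 0.422, cannot exclude fewer myofibroblasts. A Cre transgene carried by the T3KO hearts alone stays open and cannot be told apart from the deletion of Tgfb3, because 0 WT libraries and 3 T3KO libraries held Esr1 above 10 CPM. Fewer fibroblasts or vessel cells as a source of the fall and an effect of the deletion itself also stay open. So does the operation, since whether the WT hearts were operated on is not given in the sources used here. The limits of the transgene, of tamoxifen and of the operation hold for every gene and list called between T3KO and WT, not for the collagens alone. Differences between the groups in collection time or handling at dissection could also bear on other genes called, which was not tested.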
